A study of Mus musculus with 32 samples.

How the data were processed

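RNA of 5 uninjected livers and 27 liver tumours of FVB mice was sequenced. Per the series text, RNA was purified on Qiagen columns with DNase digestion, had integrity numbers of 8.5 to 10, and was made into libraries with a directional NEBNext Ultra kit. The genome build was GRCm38 (release GRCm38.p6). The aligner, the counting program and the strand setting are not given in the sources used here. The columns of the deposited table name 3 flow cells (10, 13 and 9 libraries), and those of the first alone carry the word trimmed, per the file headers.

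The deposited table holds 36333 genes. The values analysed here are the deposited total counts, which are whole numbers per gene and library and were not normalised by the authors. The RPKM values in the deposited table were used to check which samples the authors' comparison groups hold and to derive gene lengths, which could be had for 91.6% of the genes tested. The table also gives the authors' own 15 comparisons of pooled groups, with a log2 fold change, an FDR p-value and the larger of the 2 groups' mean RPKM (the column of maximum group means), from a test whose tool is not given in the sources used here. The deposited log2 fold change and FDR p-value were used only for the comparison with the authors' deposited table. The 64 columns of TPM and CPM were not used here. Since counts were present, the alternatives planned for files without counts did not apply.

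Samples were grouped by the injected plasmids as labelled, into 9 groups, and replicates were numbered within a group without any pairing. The grouping, the comparisons, their tests, the gene lists, the rule for naming genes and most alternative settings were set before the data were examined. Total counts per library were 16.5 to 28.9 M. CPM values use the TMM-scaled library size. The sex of each animal was checked against Xist and Ddx3y (32 of 32 matched). Each of the 51 pairs of libraries within a group was checked for copied data, and 0 were identical (lowest chi-square per gene 12.8).

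Differential expression was tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3). TMM factors were used, and genes were kept by filterByExpr on the groups (minimum count 10, minimum total 15), which left 16994. All 32 libraries entered a model with a mean per group and a term for sex, fitted by robust quasi-likelihood with a two-sided F test, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The common coefficient of biological variation was 0.3. Group means of B+mutant and BY+mutant weighted their 2 groups equally, and those of Y+mutant weighted each tumour equally. Errors are SE for log2 fold changes and SD for CPM. The 10 planned comparisons were joined by that of Y+mutant with B+mutant, chosen after seeing the data. Sex differences used the same model with the sex term estimated separately in livers and tumours, and the difference between the terms was tested.

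The 28 gene lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with the correlation estimated per list. They cover NRF2, Wnt and YAP targets, hepatocyte identity, fetal liver, cell cycle, glycolysis, pentose phosphate, fatty acid oxidation, oxidative phosphorylation, bile acid, urea cycle, cholesterol and fatty acid synthesis, cytochrome P450, ribosomal protein, proteasome, hypoxia, integrated stress response, chaperone and interferon genes. They also cover markers of macrophages, lymphocytes, neutrophils, endothelial cells, stellate cells, cholangiocytes and erythroid cells. With the estimated correlation and all libraries, calls held for the Wnt and cholangiocyte lists in BY+mutant against Y+mutant and for the cholangiocyte list in Y+mutant against B+mutant, and for no other list.

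Named genes were Nfe2l2, Yap1, Ctnnb1, Keap1 and Myc, up to 4 called members of each described list with the smallest adjusted p, and the 8 genes of largest change in each direction (5 in comparisons of B+mutant or Y+mutant). The last had to be called, reach 5 CPM in the higher arm and have arms that did not overlap. Some genes that meet these rules are not reported here. Genes named beside 1 library or a flow cell were chosen after their values were seen. For a gene with no count in an arm, the fold is a lower bound from a floor of 3 counts over the arm. With 1 to 3 counts, the ratio has an exact Poisson 95% interval. Intervals and floors cover counting error only.

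The alternatives were DESeq2 1.42.0 (Wald test), RLE size factors, no count filter, no sex term, only the groups compared, females only, males only, leaving out each replicate in turn, the estimated correlation and BY libraries split between comparisons. Chosen after seeing the data were a term for the flow cell, removal of each library's trend over gene length, and 2 settings without BYW replicate 2. The number of genes called was also counted in 40 splits of the libraries per comparison, the real one included (35 in the smallest). The procedure was tested on simulated data with 100 genes changed by a log2 of 1 and 100 by a log2 of 2 between BYL and BY. Of these edgeR called 63% and 73% in the right direction and 4 of 16794 unchanged genes, and DESeq2 67% and 76% and 22 unchanged genes. Raising the NRF2 list by a log2 of 1 called it with either correlation, as 1 of 2 lists called among 28. The simulated genes varied independently, so this cannot show how either setting acts on genes that move together. Figures were drawn with matplotlib 3.10.9.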

Results

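RNA sequencing was carried out on 32 mouse samples of the FVB strain, 5 livers from uninjected animals and 27 liver tumours that grew after hydrodynamic tail vein injection, a rapid injection that carries plasmid DNA into hepatocytes. The plasmids encoded Δ(90), a deletion mutant of beta-catenin, YAP, a transcriptional co-activator of the Hippo pathway, and NFE2L2, the gene of the antioxidant transcription factor NRF2, as wild type or as the mutants L30P and R34P. The 9 groups were uninjected liver (n = 5), Δ(90)+YAP (here BY, n = 5), Δ(90)+YAP+NFE2L2 wild type (BYW, n = 5), Δ(90)+YAP+L30P (BYL, n = 5), Δ(90)+YAP+R34P (BYR, n = 4), Δ(90)+L30P (BL, n = 2), Δ(90)+R34P (BR, n = 2), YAP+L30P (YL, n = 1) and YAP+R34P (YR, n = 3). BL and BR together are called B+mutant (n = 4), YL and YR together Y+mutant (n = 4), and BYL and BYR together BY+mutant (n = 9). There were 16 female and 16 male animals, and the 4 B+mutant tumours were all from females. The sex read from Xist and the Y-linked gene Ddx3y matched the label in 32 of 32 libraries.

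The deposited total counts per library lay between 16.5 and 28.9 M. By group they were 16.5 to 18.3 M for liver, 16.8 to 19.3 for BY, 18.1 to 28.9 for BYW, 19.8 to 23.6 for BYL and 19.7 to 22.9 for BYR. The smaller groups had 18.1 to 19.5 M in BL, 19.3 to 22.4 in BR, 24.3 in YL and 20.3 to 24.6 in YR. The column headers of the deposited table name 3 flow cells. All liver and BY libraries (10) were on the first, whose headers alone carry the word trimmed. The second held 13 libraries, BYW, BYL and BYR except BYR replicate 2, and the third held the 9 others, BL, BR, YL, YR and BYR replicate 2. Each comparison of BYL, BYR or BYW with BY, and of B+mutant or Y+mutant with liver, therefore lies wholly between flow cells, while BY with liver and Y+mutant with B+mutant lie within one. Mitochondrial transcripts took 0.03% to 0.21% of the counts. In the principal components of the 2000 most variable genes, the first component held 45.7% of the variance and the second 15%.

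**Figure D1:**
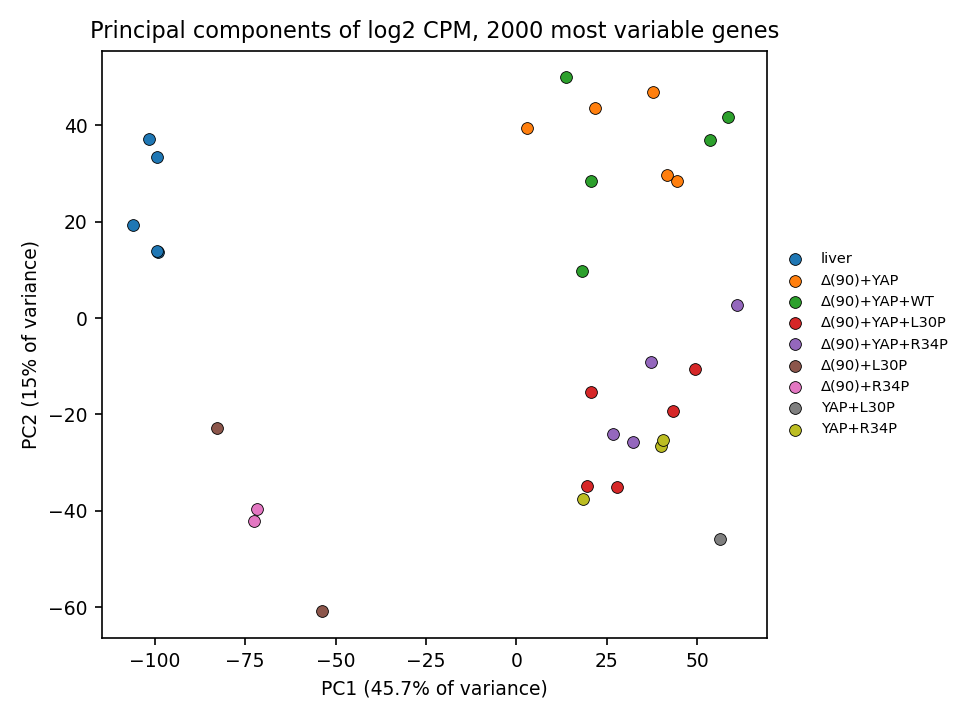
First and second principal components of log2 CPM over the 2000 most variable genes, 1 point per library, coloured by group. The axes give the component scores, and on the first the 4 B+mutant tumours lie between -82.8 and -53.8, the 5 livers between -106.1 and -99.1 and all other tumours between 2.9 and 60.9.

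Of the genes carried on the plasmids, Yap1 parted the groups with and without its plasmid in every library, and Ctnnb1 and Nfe2l2 did so by group means with overlap between libraries. Yap1 (gene ID 22601, GRCm38 chromosome 9, 7931999 to 8004596) stood at 107 ± 12.2 CPM (counts per 1e6 counts, SD, n = 5) in liver, 3530 ± 1630 in BY (n = 5), 2550 ± 915 in BY+mutant (n = 9) and 1880 ± 670 in Y+mutant (n = 4). It was at 85.6 ± 2.26 CPM in B+mutant (n = 4), whose plasmids lacked YAP. Ctnnb1, which encodes beta-catenin (gene ID 12387, chromosome 9, 120933400 to 120960507), was at 355 ± 33.7 CPM in liver, 745 ± 195 in BY and 1330 ± 290 in BY+mutant, 1280 ± 588 in B+mutant, and at 494 ± 46.9 in Y+mutant, whose plasmids lacked Δ(90). BY replicate 4, at 455 CPM, lay within the Y+mutant range of 427 to 537, and BL replicate 1 was at 558. Nfe2l2 (gene ID 18024, chromosome 2, 75675513 to 75704663) was at 78.5 ± 8.06 CPM in liver, 141 ± 45.8 in BY, 392 ± 143 in BYW, 253 ± 7.31 in BYL, 266 ± 2.47 in BYR, 187 ± 39.4 in B+mutant and 238 ± 39.7 in Y+mutant. BL replicate 1, at 131 CPM of Nfe2l2, lay within the BY range of 98.7 to 219. Counts per gene do not separate plasmid from chromosomal transcripts.

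**Figure D2:**
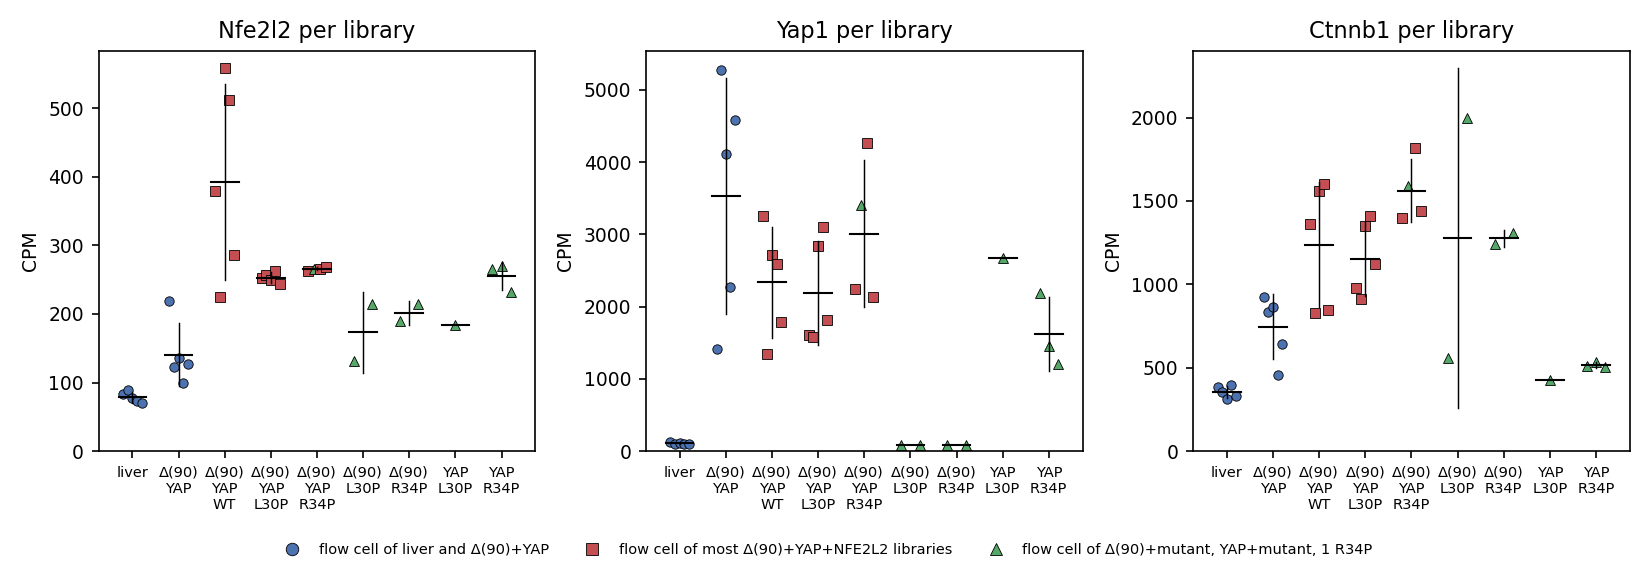
CPM of Nfe2l2, Yap1 and Ctnnb1 in each of the 32 libraries by group, with 1 point per library (marker by flow cell), a horizontal line at each group's mean and a vertical line for 1 SD on either side. Yap1 lay between 82.3 and 87.2 in the 4 B+mutant tumours and between 1210 and 2670 in the 4 Y+mutant tumours.

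Tumours of the BY group were compared with uninjected liver to describe the state that Δ(90) and YAP produce without added NFE2L2. Direct targets of the 2 plasmid-borne activators were higher. Ankrd1, a YAP target (gene ID 107765, chromosome 19, 36111965 to 36119844), stood at 133 ± 50.7 CPM in BY and 0.344 ± 0.108 in liver (log2 fold change 8.57 ± 0.48, SE, n = 5 and 5, adjusted p = 6.53e-13). Axin2, a Wnt feedback gene, was at 138 ± 59.5 against 10.5 ± 1.37 CPM (log2 3.71 ± 0.37). Of 22 YAP target genes 16 were higher and 1 lower, the same counts as adjusted over the list alone (median log2 1.94, camera adjusted p = 1.23e-09, adjusted p = 0.146 with an estimated correlation). Of 24 Wnt target and pericentral genes 13 were higher and 3 lower, also adjusted over the list alone (median 1.69, camera adjusted p = 0.00279, adjusted p = 0.402 with an estimated correlation). The NRF2 target list went the other way, with 4 of 46 higher and 17 lower, also adjusted over the list alone (median -0.42, camera adjusted p = 0.0117, adjusted p = 0.681 with an estimated correlation), among them Me1, malic enzyme, at 54.2 ± 13.3 against 244 ± 40.9 CPM.

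Genes of the fetal liver and of dividing cells were higher in BY. Fetal liver and hepatoblast genes had 10 of 15 members higher and 0 lower (11 adjusted over the list alone, median 2.36, camera adjusted p = 1.86e-05, adjusted p = 0.146 with an estimated correlation). They include Gpc3, glypican 3, at 171 ± 66.4 against 1.94 ± 0.579 CPM, and the RNA-binding protein gene Igf2bp1 at 40.4 ± 15 against 0.361 ± 0.233. Of 30 cell cycle genes 28 were higher and 0 lower, also adjusted over the list alone (median 3.02, camera adjusted p = 4.01e-12, adjusted p = 0.252 with an estimated correlation), with Foxm1 at log2 3.50 ± 0.38. Myc, also on the list of fixed genes, was at 24.7 ± 5.23 against 8.16 ± 4.96 CPM (log2 1.66 ± 0.25, adjusted p = 5.52e-06). Cholangiocyte markers had 11 of 14 higher and 1 lower, also adjusted over the list alone (median 2.88, camera adjusted p = 6.76e-05, adjusted p = 0.146 with an estimated correlation), among them Epcam at 61.3 ± 17.5 against 1.28 ± 0.288 CPM. Integrated stress response genes had 11 of 15 higher and 1 lower, also adjusted over the list alone (median 2.40, camera adjusted p = 0.000486, adjusted p = 0.252 with an estimated correlation). Of these, Phgdh, the first enzyme of serine synthesis, stood at 60.9 ± 16 against 0.816 ± 0.183 CPM.

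Functions of the adult hepatocyte were lower. Of 22 hepatocyte identity genes 16 were lower and 0 higher (17 adjusted over the list alone, median -1.40, camera adjusted p = 2.53e-07, adjusted p = 0.252 with an estimated correlation), with Ttr, transthyretin, at 1310 ± 314 against 7270 ± 1030 CPM. All 7 urea cycle genes were lower, also adjusted over the list alone (median -3.27, camera adjusted p = 0.000128, adjusted p = 0.252 with an estimated correlation), with Cps1 at 473 ± 532 against 5400 ± 1350 CPM. All 25 oxidative phosphorylation genes were lower, also adjusted over the list alone (median -1.14, camera adjusted p = 8.81e-19, adjusted p = 0.146 with an estimated correlation). So were 20 of 21 fatty acid oxidation genes (median -1.04, camera adjusted p = 1.37e-11, adjusted p = 0.23 with an estimated correlation) and 12 of 13 bile acid genes (median -1.5, camera adjusted p = 2.67e-05, adjusted p = 0.252 with an estimated correlation), counts that held when adjusted over the list alone. Xenobiotic cytochrome P450 genes had 14 of 19 lower (14 adjusted over the list alone, median -2.78, camera adjusted p = 6.82e-05, adjusted p = 0.378 with an estimated correlation), and Cyp2b10 was at 0.0616 ± 0.0887 against 64.9 ± 55 CPM. Fatty acid synthesis genes had 10 of 12 lower (10 adjusted over the list alone, median -1.59, camera adjusted p = 6.01e-05, adjusted p = 0.252 with an estimated correlation). Cholesterol synthesis genes had 7 of 21 lower and 1 higher, also adjusted over the list alone (median -0.21, camera adjusted p = 0.0402, adjusted p = 0.681 with an estimated correlation).

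Ribosomal protein genes were higher in BY, 39 of 42 with 1 lower (40 and 1 adjusted over the list alone, median 0.62, camera adjusted p = 4.94e-05, adjusted p = 0.565 with an estimated correlation). Interferon response genes had 12 of 16 higher, also adjusted over the list alone (median 1.23, camera adjusted p = 0.000252, adjusted p = 0.31 with an estimated correlation), with Ifit2 at 35.6 ± 7.44 against 3 ± 1.3 CPM. Proteasome genes had 17 of 27 lower, also adjusted over the list alone (median -0.29, camera adjusted p = 0.000486, adjusted p = 0.467 with an estimated correlation). Endothelial cell markers had 8 of 14 lower, also adjusted over the list alone (median -1.05, camera adjusted p = 0.0144, adjusted p = 0.509 with an estimated correlation), Tek among them at 4.67 ± 1 against 17.2 ± 0.587 CPM. Camera called no other list. These were glycolysis (3 of 19 higher, 6 lower, adjusted p = 0.157), pentose phosphate (0 of 7 higher, 2 lower, 0.375), hypoxia (4 of 14 higher, 2 lower, 0.769) and endoplasmic reticulum chaperone genes (0 of 16 higher, 3 lower, 0.244). The cell markers not called were those of macrophages (2 of 12 higher, adjusted p = 0.83), lymphocytes (1 of 13 higher, 2 lower, 0.473), neutrophils (4 of 10 higher, 0.429), stellate cells (5 of 15 higher, 2 lower, 0.732) and erythroid cells (1 of 8 higher, 1 lower, 0.83). Adjusted over the list alone, the counts of these 9 lists were the same save 3 hypoxia genes higher.

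The edgeR test called 8670 of 16994 genes between BY and liver at an adjusted p under 0.05, 4904 higher and 3766 lower. Among the largest differences, Hs3st2, a heparan sulfate sulfotransferase gene, had no count in any liver and was at least 369-fold higher in BY, and Pla2g5, a phospholipase gene, was 2140-fold higher (95% counting interval 383 to 84400). The major urinary protein gene Mup19 was at 1.47 ± 2.39 against 635 ± 824 CPM. Such intervals and floors cover counting error only. Between the males alone the count was 5583. The glycolysis and erythroid lists had medians of 0.19 and 0.42 and means of 0.07 and 0.60 but a camera direction of down, and the stellate list a median of -0.01 with a mean of 0.15.

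The mutants L30P and R34P were added to Δ(90) and YAP in BYL and BYR, which were compared with BY to ask what mutant NFE2L2 adds to those tumours. NRF2 targets were higher in both. Of 46 such genes 40 were higher and 1 lower in BYL (41 and 1 adjusted over the list alone, median log2 1.74, camera adjusted p = 1.67e-30, adjusted p = 0.108 with an estimated correlation). In BYR 39 were higher and 0 lower (40 and 0 adjusted over the list alone, median 1.59, camera adjusted p = 7.24e-31, adjusted p = 0.102 with an estimated correlation). Txnrd1, thioredoxin reductase (gene ID 50493, chromosome 10, 82833951 to 82897724), was at 824 ± 116 CPM in BYL (n = 5), 901 ± 174 in BYR (n = 4) and 207 ± 31 in BY (n = 5), a log2 fold change of 1.99 ± 0.19 and 2.12 ± 0.20. Slc7a11, the cystine transporter (gene ID 26570, chromosome 3, 50364936 to 50499087), was at 445 ± 126, 329 ± 136 and 2.31 ± 1.03 CPM. The glutathione transferase gene Gsta1 was at 1160 ± 342, 929 ± 361 and 0.858 ± 0.561 CPM.

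**Figure D3:**
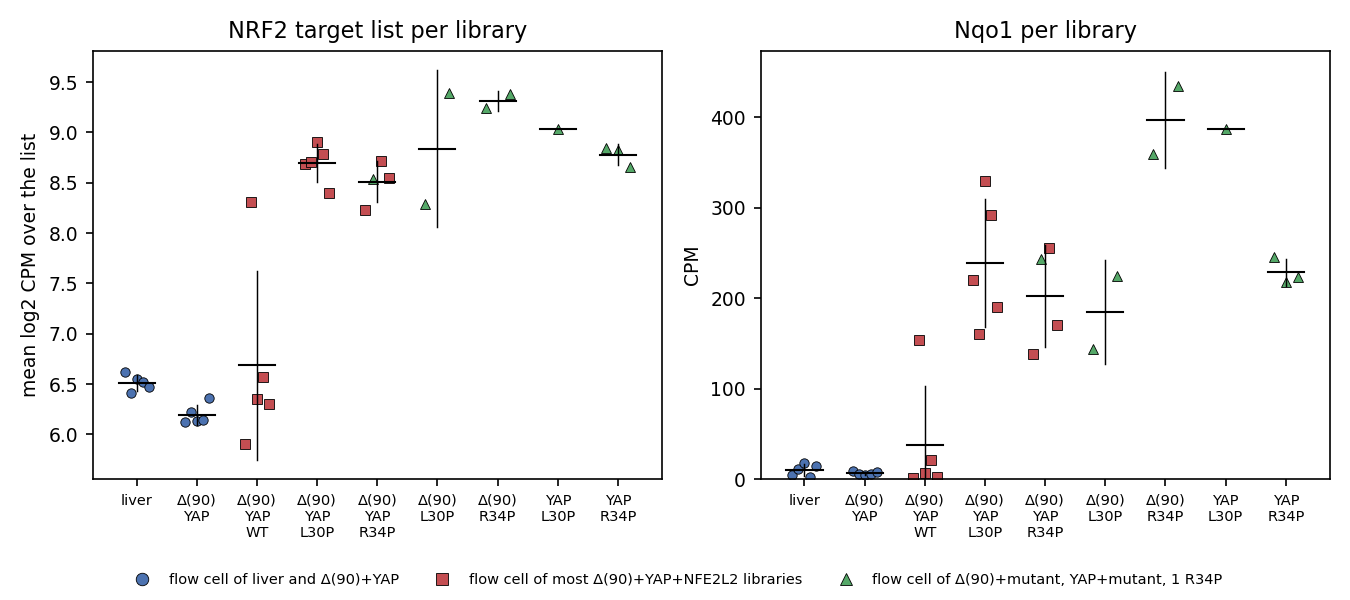
Mean log2 CPM over the 46 NRF2 target genes (left) and CPM of Nqo1, one of them (right, SD shown down to 0), with 1 point per library (marker by flow cell), a horizontal line at each group's mean and a vertical line for 1 SD on either side. On the left the 5 BY libraries lie between 6.12 and 6.36, BYW replicate 2 at 8.31 and the other BYW libraries between 5.90 and 6.57.

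Pentose phosphate, glycolysis and stress response genes were higher with either mutant. Pentose phosphate genes had 6 of 7 higher in BYL (6 adjusted over the list alone, median 0.91, camera adjusted p = 6.91e-06, adjusted p = 0.108 with an estimated correlation). In BYR 6 were higher (7 adjusted over the list alone, median 0.70, camera adjusted p = 2.15e-06, adjusted p = 0.0814 with an estimated correlation). Of these 7 genes 4 are also on the NRF2 list. Tkt, transketolase, was at 462 ± 35.5 CPM in BYL, 472 ± 27.5 in BYR and 168 ± 14.7 in BY. Glycolysis genes had 9 of 19 higher and 1 lower in BYL (11 and 1 adjusted over the list alone, median 0.63, camera adjusted p = 0.000594, adjusted p = 0.389 with an estimated correlation). In BYR 9 were higher (10 adjusted over the list alone, median 0.56, camera adjusted p = 3.82e-05, adjusted p = 0.218 with an estimated correlation), with the glucose transporter gene Slc2a1 at 49.2 ± 10.5, 53.8 ± 10.2 and 14.1 ± 2.62 CPM. Integrated stress response genes had 12 of 15 higher and 1 lower in each, also adjusted over the list alone (median 1.40 and 1.62). Their camera adjusted p was 1.83e-05 in BYL, with adjusted p = 0.209 with an estimated correlation, and 2.15e-06 in BYR, with adjusted p = 0.133 with an estimated correlation. Psat1, a serine synthesis enzyme, was at 111 ± 25.1, 114 ± 17 and 23.7 ± 6.24 CPM. Hypoxia genes had 4 of 14 higher and 1 lower in each, also adjusted over the list alone (camera adjusted p = 0.0361, adjusted p = 0.389 with an estimated correlation in BYL, and 0.0198, adjusted p = 0.321 with an estimated correlation in BYR), Adm, adrenomedullin, at 14.1 ± 4.07, 14.6 ± 5.91 and 1.62 ± 0.993 CPM.

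Cholesterol synthesis genes had 5 of 21 lower and 1 higher in BYL, also adjusted over the list alone, without a camera call (adjusted p = 0.073). In BYR 6 were lower, also adjusted over the list alone (median -0.40, camera adjusted p = 0.00263, adjusted p = 0.754 with an estimated correlation). Wnt target and pericentral genes had 8 of 24 lower and 2 higher in BYL (9 and 2 adjusted over the list alone, median -0.72, camera adjusted p = 0.0494, adjusted p = 0.753 with an estimated correlation). In BYR 10 were lower (16 lower and 1 higher adjusted over the list alone, median -1.12, or -1.01 with the 1 gene that had an arm at 0 set at its bound, camera adjusted p = 0.000935, adjusted p = 0.486 with an estimated correlation). Rnf43, a Wnt feedback gene, was at 83.0 ± 16.1, 83.7 ± 12.8 and 147 ± 38.7 CPM. Cholangiocyte markers had 5 of 14 lower in BYL (6 adjusted over the list alone, median -0.96, camera adjusted p = 0.0175, adjusted p = 0.389 with an estimated correlation). In BYR 3 were lower, also adjusted over the list alone (median -0.49, camera adjusted p = 0.045, adjusted p = 0.588 with an estimated correlation). Cldn7, a claudin gene, was at 2.72 ± 3.13, 4.46 ± 4.41 and 21.7 ± 6.86 CPM.

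Neutrophil markers were higher in BYL, 10 of 10, also adjusted over the list alone (median 4.14, unchanged with 1 gene at its bound, camera adjusted p = 3.28e-08, adjusted p = 0.11 with an estimated correlation). In BYR 9 were higher (10 adjusted over the list alone, median 3.57, unchanged at the bound, camera adjusted p = 2.34e-07, adjusted p = 0.133 with an estimated correlation). Mmp9, a matrix metalloproteinase gene (gene ID 17395, chromosome 2, 164940744 to 164955850), was at 25.1 ± 8.74, 16.9 ± 10.8 and 0.721 ± 0.549 CPM, and S100a8, a neutrophil calprotectin gene, at 20.9 ± 14.7 CPM in BYL and 1.93 ± 1.23 in BY. In BYR replicate 2, the library on another flow cell, S100a8 was at 1.31 CPM against 13.4 to 21.4 in the 3 other BYR libraries, and Mmp9 was at 10.7 against 11.3 to 33.0. Ribosomal protein genes were lower, 23 of 42 with 2 higher in BYL (25 and 2 adjusted over the list alone, median -0.44, camera adjusted p = 3.75e-05, adjusted p = 0.753 with an estimated correlation). In BYR 18 were lower and 1 higher (19 and 1 adjusted over the list alone, median -0.26, camera adjusted p = 0.00368, adjusted p = 0.756 with an estimated correlation). With each library's trend over gene length removed, an alternative added after the data were seen, these medians were -0.12 (adjusted p = 0.213) and -0.02 (adjusted p = 0.437). The histone gene Hist1h2ao, at 70.7 ± 21.8 CPM in BY on the first flow cell, was at 0.128 ± 0.158 in BYL and 0.215 ± 0.2 in BYR.

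**Figure D4:**
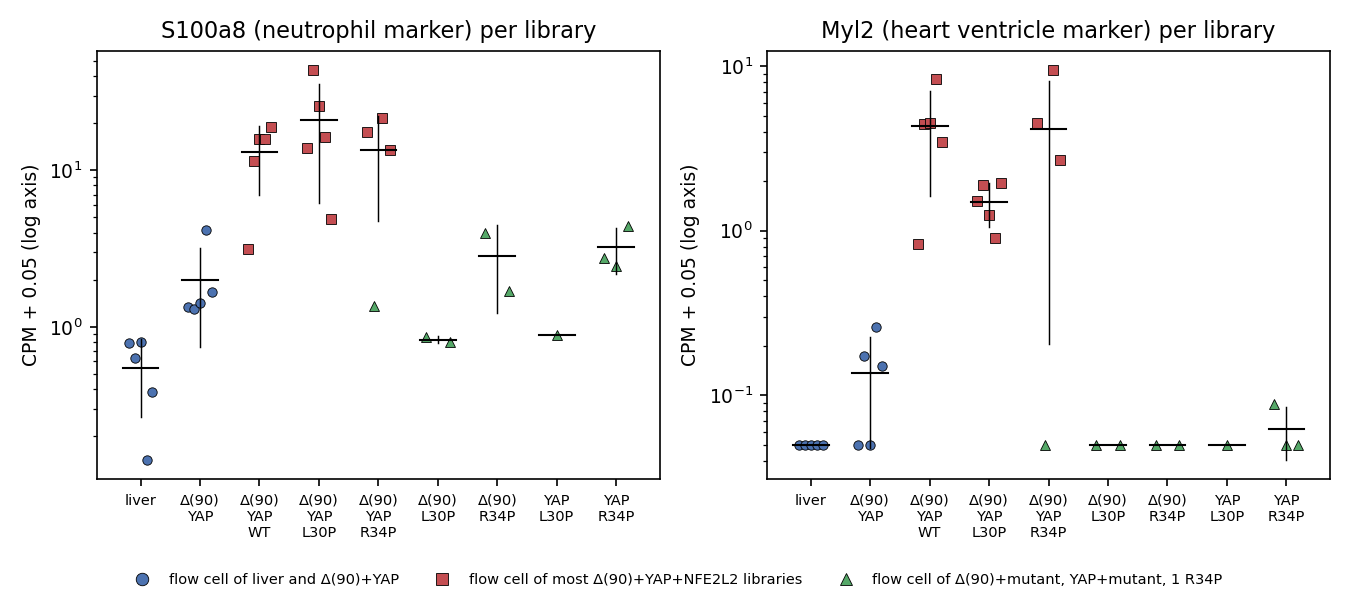
CPM plus 0.05 (log axis) of the neutrophil marker S100a8 and the heart muscle marker Myl2 in each library by group, 1 point per library (marker by flow cell), a horizontal line at each group's mean and a vertical line for 1 SD on either side. Myl2 lies between 0.781 and 9.38 in the 13 libraries of the second flow cell and at 0.209 or less in the 19 others.

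The test called 5813 genes between BYL and BY, 2741 higher and 3072 lower, and 4388 between BYR and BY, 2196 higher and 2192 lower. Females alone gave 3369 and 2318 and males alone 3220 and 1740, and without BYR replicate 4 the count for BYR was 2850. The largest differences included Brinp3, a neuronal gene without a count in BY and at least 416-fold higher in BYL and 253-fold higher in BYR. The sodium and glucose cotransporter gene Slc5a1 was at 1.89 ± 0.428, 2.78 ± 2.01 and 32.5 ± 10.7 CPM, and the collagen gene Col4a3 at 0.737 ± 0.739, 1.5 ± 0.887 and 15.9 ± 4.93 CPM. In either comparison the groups lie on different flow cells and cannot be told apart from them by these libraries alone. BYW shares the flow cell of BYL, and its mean log2 CPM over the NRF2 targets was 8.31 in replicate 2 and 5.90 to 6.57 in the others. That mean was 6.12 to 6.36 in BY, 8.40 to 8.90 in BYL and 8.23 to 8.72 in BYR. For the NRF2 list these values argue against the flow cell as the source of the difference. The hepatocyte identity list had a median of -0.14 and a mean of 0.05 in BYL and of -0.10 and 0.01 in BYR, and the bile acid list a median of -0.03 and a mean of 0.21 in BYR.

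Wild-type NFE2L2 was added in BYW, whose comparison with BY asks what raising the normal gene does. Nfe2l2 itself was higher, at 392 ± 143 against 141 ± 45.8 CPM (log2 1.48 ± 0.20, n = 5 and 5, adjusted p = 2.97e-05). NRF2 targets had 14 of 46 higher and 2 lower (22 and 2 adjusted over the list alone, median 0.49, camera adjusted p = 5.85e-05, adjusted p = 0.691 with an estimated correlation). Those values rest on 1 tumour, BYW replicate 2, without which the median was 0.20 and the camera adjusted p was 0.186. In that tumour Slc7a11 was at 295 CPM, against 0.729 to 4.33 in the 4 other BYW tumours. Gclc, the catalytic subunit of the first enzyme of glutathione synthesis, was at 1660 CPM in it and at 196 to 304 in the others. The fetal liver gene Afp, alpha-fetoprotein, was likewise at 2680 CPM in replicate 2 and at 3.68 to 8.94 in the others, and its log2 difference from BY, 4.93 ± 1.47, was -1.06 without that tumour (adjusted p = 0.217).

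Ribosomal protein genes were lower in BYW, 30 of 42 (33 adjusted over the list alone, median -0.57, camera adjusted p = 8.26e-22, adjusted p = 0.302 with an estimated correlation), with Rps16 at 235 ± 52.7 against 505 ± 123 CPM. With the trend over gene length removed the median was -0.25 (adjusted p = 3.69e-09). Neutrophil markers had 9 of 10 higher, also adjusted over the list alone (median 3.16, or 3.11 with 1 gene at its bound, camera adjusted p = 3.56e-09, adjusted p = 0.216 with an estimated correlation), with S100a8 at 13 ± 6.13 against 1.93 ± 1.23 CPM across the flow cells. The heart muscle marker Myh7 was also higher, at 5.67 ± 4.26 against 0.0395 ± 0.0432 CPM. Markers of other cells of the liver were lower, and lowest in BYW replicate 5. Its mean log2 CPM was 0.51 over the stellate markers (3.32 to 3.78 in the other BYW tumours), -0.05 over the endothelial (2.40 to 3.44) and 2.23 over the macrophage markers (3.04 to 5.26). Without it 7, 6 and 1 of these markers were lower. The medians were then -1.07 (camera adjusted p = 3.9e-05, adjusted p = 0.3 with an estimated correlation), -0.81 (6.64e-05, adjusted p = 0.329 with an estimated correlation) and -0.53, the last no longer called (adjusted p = 0.216). Stellate cell and fibroblast markers had 8 of 15 lower (12 adjusted over the list alone, median -1.37, camera adjusted p = 3.9e-07, adjusted p = 0.302 with an estimated correlation), with Lum, lumican, at 6.12 ± 4.11 against 17.9 ± 2.98 CPM. Endothelial cell markers had 7 of 14 lower (9 adjusted over the list alone, median -1.09, camera adjusted p = 1.43e-06, adjusted p = 0.302 with an estimated correlation), with Stab2 at 11.6 ± 6.76 against 30.8 ± 9.59 CPM. Macrophage markers had 2 of 12 lower, also adjusted over the list alone (median -0.81, camera adjusted p = 0.0175, adjusted p = 0.691 with an estimated correlation). Hepatocyte identity genes had 4 of 22 higher (7 adjusted over the list alone, median 0.56, camera adjusted p = 0.000241, adjusted p = 0.691 with an estimated correlation), Apob among them at 4340 ± 913 against 2440 ± 434 CPM. The mean log2 CPM over this list overlapped between the groups, at 9.25 to 10.61 in BYW and 9.16 to 10.28 in BY.

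In all, 2360 genes were called between BYW and BY, 1132 higher and 1228 lower, and 1934 without BYW replicate 2. With only the BYW and BY libraries in the model 238 genes were called, 65 higher and 173 lower, and another division of the same 10 libraries gave 407. As between BYL and BY, flow cell and group cannot be told apart. The proteasome list had a median of 0.02 and a mean of -0.06.

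BYL and BYR were compared with each other to ask whether the L30P and R34P mutants differ in their effect. No gene was called by edgeR, with 529 of 16994 at an unadjusted p under 0.05 and a smallest adjusted p of 0.34, while DESeq2 called 4. Nfe2l2 differed by a log2 of -0.07 ± 0.21 (SE, n = 5 and 4) and Myc by 0 ± 0.25. Camera called 10 of 28 lists and none with an estimated correlation. The strongest was that of endothelial cell markers (0 of 14 called, also adjusted over the list alone, median 0.62, camera adjusted p = 5.84e-08, adjusted p = 0.583 with an estimated correlation), followed by stellate cell markers (0 of 15, median 0.52, camera adjusted p = 9.34e-05, adjusted p = 0.815 with an estimated correlation). NRF2 targets had a median of 0.16 (0 of 46 called, also adjusted over the list alone, camera adjusted p = 0.00345, adjusted p = 0.844 with an estimated correlation). The hypoxia and integrated stress response lists had medians of -0.05 and -0.04 with means of 0.05 and 0.01, and the lymphocyte list a median of 0.01 with a mean of -0.23. In simulated data for 5 BYL and 5 BY libraries, the test called 63% of genes changed by a log2 of 1 and 73% of those changed by 2, and 5 against 4 was not simulated.

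The tumours with mutant NFE2L2, BYL and BYR, were set against those with the wild-type gene, BYW, to separate the effect of the mutations from that of added NFE2L2. Of these 14 libraries 13 shared a flow cell. Nfe2l2 itself was lower with the mutants, at 259 ± 8.65 (n = 9) against 392 ± 143 CPM (n = 5, log2 -0.60 ± 0.17, adjusted p = 0.0154), while its targets were higher. Of 46 NRF2 targets 32 were higher and 1 lower (38 and 1 adjusted over the list alone, median 1.22, camera adjusted p = 5.56e-28, adjusted p = 0.084 with an estimated correlation). Within the shared flow cell and without BYW replicate 2, a setting added after the data were seen, the median was 1.61. Txnrd1 was at 859 ± 141 against 272 ± 80.3 CPM (log2 1.64 ± 0.18, adjusted p = 1.77e-06) and Gsr, glutathione reductase, at 381 ± 64 against 106 ± 49.1.

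Stress response, pentose phosphate and glycolysis genes were higher with the mutants. Integrated stress response genes had 9 of 15 higher (10 adjusted over the list alone, median 1.20, camera adjusted p = 2.74e-07, adjusted p = 0.084 with an estimated correlation), with Psat1 at 112 ± 20.6 against 17.7 ± 10.5 CPM and the mitochondrial folate enzyme gene Aldh1l2 at 31.5 ± 11.1 against 1.85 ± 0.941. Pentose phosphate genes had 4 of 7 higher, also adjusted over the list alone (median 0.61, camera adjusted p = 1.11e-05, adjusted p = 0.084 with an estimated correlation). Glycolysis genes had 9 of 19 higher and 1 lower (9 and 2 adjusted over the list alone, median 0.42, camera adjusted p = 0.00114, adjusted p = 0.438 with an estimated correlation). Pkm, pyruvate kinase M, was at 144 ± 41.4 against 52.1 ± 23.9 CPM. Lipid synthesis genes were lower, 13 of 21 cholesterol synthesis genes (15 adjusted over the list alone, median -0.53, camera adjusted p = 2.66e-06, adjusted p = 0.453 with an estimated correlation). So were 6 of 12 fatty acid synthesis genes (9 adjusted over the list alone, median -0.74, camera adjusted p = 0.000123, adjusted p = 0.438 with an estimated correlation). Scd1, stearoyl-CoA desaturase, was at 530 ± 261 against 2360 ± 893 CPM. Cell cycle genes had 6 of 30 higher (5 adjusted over the list alone, median 0.68, camera adjusted p = 1.79e-07, adjusted p = 0.453 with an estimated correlation), Rrm2 at 34.7 ± 6.38 against 14.3 ± 7.88 CPM. Hepatocyte identity genes had 7 of 22 lower and 1 higher (12 and 2 adjusted over the list alone, median -0.49, camera adjusted p = 0.00361, adjusted p = 0.515 with an estimated correlation), among them the fibrinogen genes Fga, Fgb and Fgg.

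Markers of macrophages and endothelial cells were higher with the mutants. Without BYW replicate 5, the lowest BYW tumour in both, 5 of 12 and 2 of 14 were higher (medians 1.13 and 0.60, camera adjusted p = 3.04e-06 and 6.83e-05, each with adjusted p = 0.291 with an estimated correlation). Macrophage and Kupffer cell markers had 6 of 12 higher (10 adjusted over the list alone, median 1.39, camera adjusted p = 6.76e-07, adjusted p = 0.291 with an estimated correlation), with the complement gene C1qa at 146 ± 32 against 51.3 ± 24 CPM. Endothelial cell markers had 5 of 14 higher (6 higher and 1 lower adjusted over the list alone, median 0.88, camera adjusted p = 5.54e-06, adjusted p = 0.304 with an estimated correlation), Lyve1 at 11.6 ± 5.09 against 1.27 ± 1.27 CPM. Of 10 neutrophil markers only Mmp9 was called, also adjusted over the list alone, at 21.4 ± 10 against 3.70 ± 2.52 CPM (camera adjusted p = 0.132). Erythroid markers had 4 of 8 lower, also adjusted over the list alone (median -1.45, camera adjusted p = 0.00493, adjusted p = 0.453 with an estimated correlation), with Hba-a1 at 435 ± 227 against 1500 ± 1030 CPM. Of the fetal liver genes Mest was higher (log2 2.36 ± 0.39) and Igf2 lower (log2 -5.67 ± 1.23), the latter at 0.405 to 813 CPM across the BYW tumours and 1.10 to 15.4 across BY+mutant. The lower Igf2 rests on BYW replicates 2 and 4, at 813 and 100 CPM, while the other BYW tumours were at 0.405 to 1.41.

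The number of genes called was 3559, 1630 higher and 1929 lower. Dusp18, a phosphatase gene, was at 8.76 ± 3.26 against 0.273 ± 0.0989 CPM, and Ptgs2, which encodes cyclooxygenase 2, at 24.8 ± 16 against 0.771 ± 1.45. The keratin gene Krt5 was at 11.2 ± 3.74 against 0.586 ± 0.57. The females alone gave 618 genes and the males alone 1334, with 1 BYW female. The fetal liver, cytochrome P450 and lymphocyte lists had medians of -0.47, -0.45 and -0.16, with means of -0.73, -0.06 and 0.04 and a camera direction of up.

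**Figure D5:**
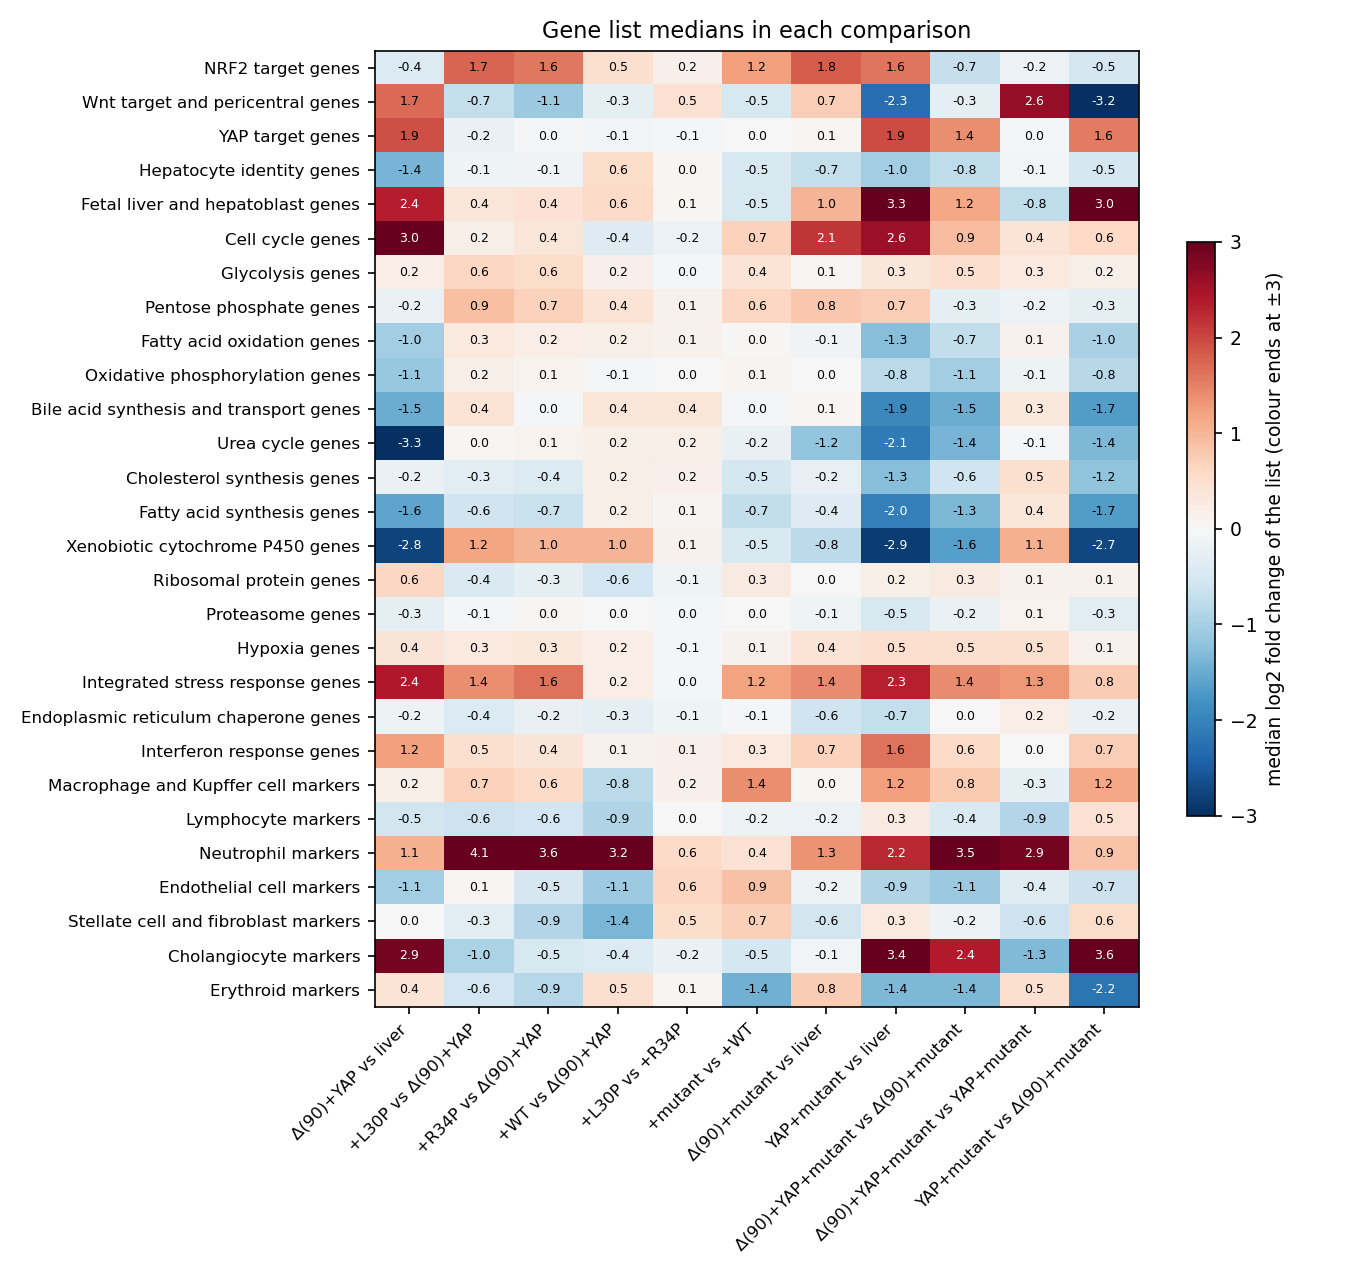
Median log2 fold change of each of the 28 gene lists (down) in each of the 11 comparisons (across), printed in each cell and coloured from blue (lower in the first group named) to red (higher), with groups named by their plasmids. The NRF2 target list has medians of 1.74 in BYL against BY, 0.49 in BYW against BY and -0.42 in BY against liver.

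B+mutant tumours, which carried mutant NFE2L2 with Δ(90) and no YAP, were compared with liver. NRF2 targets were higher, 38 of 46 with 1 lower (39 and 1 adjusted over the list alone, median 1.81, camera adjusted p = 4.92e-28, adjusted p = 0.149 with an estimated correlation), with Gstm1 at 17600 ± 7780 (n = 4) against 1610 ± 356 CPM (n = 5). Slc22a12, the urate transporter gene (gene ID 20521, chromosome 19, 6535854 to 6543070), was at 1350 ± 643 CPM and had no count in liver, at least a 29500-fold difference. Cell cycle genes had 26 of 30 higher (27 adjusted over the list alone, median 2.14, camera adjusted p = 3.98e-19, adjusted p = 0.335 with an estimated correlation). Wnt target and pericentral genes had 7 of 24 higher and 1 lower (8 and 1 adjusted over the list alone, median 0.73, also with 1 gene at its bound, camera adjusted p = 0.0169, adjusted p = 0.656 with an estimated correlation). YAP targets were not called as a list (7 of 22 higher and 2 lower, 8 and 2 adjusted over the list alone, camera adjusted p = 0.143). Interferon response genes had 7 of 16 higher (8 adjusted over the list alone, median 0.70, camera adjusted p = 1.45e-05, adjusted p = 0.467 with an estimated correlation), with Usp18 at 19.2 ± 5.68 against 2.63 ± 1.77 CPM. Hepatocyte identity genes had 11 of 22 lower (12 adjusted over the list alone, median -0.72, camera adjusted p = 0.000258, adjusted p = 0.656 with an estimated correlation). BL replicate 1 lay within the liver range here, at a mean log2 CPM of 11.14 against 11.11 to 11.40 in liver. The other B+mutant tumours were at 9.75 to 10.24. Over the NRF2 targets it was at 8.29, against 9.24 to 9.39 in those tumours and 6.41 to 6.62 in liver. The oxidative phosphorylation genes, all lower in BY, had 3 of 25 higher and 0 lower (2 higher adjusted over the list alone, camera adjusted p = 0.834). Of the neutrophil markers 1 was called, Ly6g, also adjusted over the list alone, without a count in liver and at least 37.2-fold higher (list median 1.34, also with that gene at its bound, camera adjusted p = 0.0258, adjusted p = 0.656 with an estimated correlation). There were 4255 genes called, 2326 higher and 1929 lower, and 2343 without BL replicate 2. The arms lie on different flow cells, and all 4 tumours but 3 of 5 livers were female. The oxidative phosphorylation, bile acid, macrophage and endothelial lists had medians and means of opposite sign (-0.02 and 0.04, 0.05 and -0.07, 0.03 and -0.02, and -0.16 and 0.06).

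Y+mutant tumours, with YAP and mutant NFE2L2 but no Δ(90), were compared with liver. NRF2 targets had 35 of 46 higher and 5 lower, also adjusted over the list alone (median 1.60, camera adjusted p = 3.79e-06, adjusted p = 0.396 with an estimated correlation), with the prostaglandin reductase gene Ptgr1 at 92.4 ± 38.5 (n = 4) against 4.87 ± 0.984 CPM (n = 5). YAP targets had 17 of 22 higher and 2 lower, also adjusted over the list alone (median 1.95, camera adjusted p = 3.07e-08, adjusted p = 0.261 with an estimated correlation). Wnt target and pericentral genes were lower, 16 of 24 with 2 higher, also adjusted over the list alone (median -2.29, camera adjusted p = 4.46e-05, adjusted p = 0.269 with an estimated correlation). The mean log2 CPM over this list was 0.47 in the YL tumour, 2.82 to 4.08 in the 3 YR tumours and 4.40 to 4.74 in liver, and without YL the median was -1.38 (camera adjusted p = 0.00492, adjusted p = 0.356 with an estimated correlation). Tbx3, a Wnt-dependent transcription factor gene, was at 7.44 ± 3.87 against 35.2 ± 2.4 CPM and the pericentral Cyp2e1 at 788 ± 760 against 5760 ± 1220. Fetal liver genes had 12 of 15 higher, also adjusted over the list alone (median 3.32, camera adjusted p = 2.71e-07, adjusted p = 0.147 with an estimated correlation). Cholangiocyte markers had 10 of 14 higher and 1 lower, also adjusted over the list alone (median 3.40, camera adjusted p = 2.42e-05, adjusted p = 0.158 with an estimated correlation), with Krt7, a biliary keratin gene, at 174 ± 46.1 against 0.741 ± 0.449 CPM. All 25 oxidative phosphorylation genes were lower, also adjusted over the list alone (median -0.80, camera adjusted p = 4.46e-09, adjusted p = 0.269 with an estimated correlation). So were 19 of 21 cholesterol synthesis genes, also adjusted over the list alone (median -1.28, camera adjusted p = 7.76e-08, adjusted p = 0.269 with an estimated correlation). Neutrophil markers had 6 of 10 higher, also adjusted over the list alone (median 2.25, or 2.18 with 1 gene at its bound, camera adjusted p = 0.0726). Without YL 8 were higher (camera adjusted p = 0.0305, adjusted p = 0.431 with an estimated correlation). The test called 9681 genes, 5216 higher and 4465 lower, across different flow cells. The pancreatic trypsin inhibitor gene Spink1 and the peptide hormone gene Apela had no count in liver and were at least 2670-fold and 1660-fold higher. The glycolysis, stellate and lymphocyte lists had medians of 0.34, 0.29 and 0.26 with a camera direction of down.

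BY+mutant tumours were set against B+mutant tumours to show what YAP adds. YAP targets had 15 of 22 higher and 1 lower (16 and 1 adjusted over the list alone, median 1.40, camera adjusted p = 4.03e-08, adjusted p = 0.165 with an estimated correlation), with Ankrd1 at 155 ± 48.6 (n = 9) against 1.06 ± 0.54 CPM (n = 4). Cholangiocyte markers had 10 of 14 higher and 1 lower, also adjusted over the list alone (median 2.39, camera adjusted p = 5.68e-05, adjusted p = 0.12 with an estimated correlation), with Sox9, a biliary transcription factor gene, at 29.7 ± 12.2 against 2.47 ± 1.17 CPM. Fetal liver genes had 6 of 15 higher and 1 lower, also adjusted over the list alone (median 1.16, camera adjusted p = 2.25e-05, adjusted p = 0.12 with an estimated correlation), with Gpc3 at 396 ± 80.3 against 1.48 ± 0.84 CPM. Integrated stress response genes had 13 of 15 higher and 1 lower, also adjusted over the list alone (median 1.41, camera adjusted p = 1.32e-05, adjusted p = 0.165 with an estimated correlation), with Phgdh at 173 ± 36.1 against 2.47 ± 2.12 CPM. All 25 oxidative phosphorylation genes were lower, also adjusted over the list alone (median -1.05, camera adjusted p = 2.6e-23, adjusted p = 0.12 with an estimated correlation). NRF2 targets had 22 of 46 lower and 3 higher, also adjusted over the list alone (median -0.69, camera adjusted p = 0.00343, adjusted p = 0.638 with an estimated correlation), with Mgst1 at 1160 ± 182 against 2580 ± 603 CPM. BL replicate 1, which lay within the liver range over the hepatocyte identity genes, had a mean log2 CPM of 8.29 over the NRF2 targets. That is within the BY+mutant range of 8.23 to 8.90, while the other B+mutant tumours were at 9.24 to 9.39. Neutrophil markers had 9 of 10 higher, also adjusted over the list alone (median 3.49, camera adjusted p = 0.00343, adjusted p = 0.473 with an estimated correlation), where 8 of the 9 BY+mutant libraries were on the second flow cell and all 4 B+mutant libraries on the third. Genes called numbered 7660, 4068 higher and 3592 lower. With a term for the flow cell, added after the data were seen, 1828 were called, and S100a8 had a log2 fold change of -0.04 in place of 3.48.

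BY+mutant tumours were set against Y+mutant tumours to show what Δ(90) adds. Wnt target and pericentral genes had 17 of 24 higher and 1 lower (18 and 1 adjusted over the list alone, median 2.64), a call that held with an estimated correlation (camera adjusted p = 1.13e-25 and 0.00216). Without YL the median was 1.94 (1.59e-12 and 0.0401). Tbx3 was at 73.7 ± 9.35 (n = 9) against 7.44 ± 3.87 CPM (n = 4) and Lgr5, an R-spondin receptor gene, at 24.8 ± 9.24 against 1.46 ± 1.8. Cholangiocyte markers had 10 of 14 lower and 1 higher, also adjusted over the list alone (median -1.32), a call that also held (camera adjusted p = 1.24e-06 and 0.0442), with the chloride channel gene Cftr at 0.159 ± 0.105 against 4.95 ± 1.99 CPM. The YL tumour, at a mean log2 CPM of 2.49 over these markers, lay within the BY+mutant range of 2.27 to 3.09, unlike the 3 YR tumours (4.24 to 4.69), and without it the median was -1.78. Cholesterol synthesis genes had 10 of 21 higher, also adjusted over the list alone (median 0.48, camera adjusted p = 3.75e-05, adjusted p = 0.776 with an estimated correlation), and 12 without YL (median 0.76). Integrated stress response genes had 12 of 15 higher (13 adjusted over the list alone, median 1.30, camera adjusted p = 2.19e-06, adjusted p = 0.154 with an estimated correlation). Here too YL, at 6.23, lay within the BY+mutant range of 5.70 to 6.46, unlike YR (4.19 to 4.72). Without YL the median was 1.96, and the call held with an estimated correlation (adjusted p = 0.0483). NRF2 targets were not called as a list (2 of 46 higher and 4 lower, also adjusted over the list alone, median -0.17, camera adjusted p = 0.312). The mast cell protease genes Mcpt4, Tpsb2 and Cma1 were at 10.2 ± 10.5, 12.9 ± 16 and 6.17 ± 5.99 CPM in Y+mutant and had 1, 2 and 2 counts over the 9 BY+mutant tumours. Their ratios were 2170 (95% counting interval 390 to 85800), 1380 (381 to 11400) and 657 (182 to 5430). Neutrophil markers had 9 of 10 higher, also adjusted over the list alone (median 2.86, camera adjusted p = 7.1e-05, adjusted p = 0.382 with an estimated correlation), across the same pair of flow cells as above. With a term for the flow cell, the direction of S100a8 reversed here, as given below. The number called was 3414, 1580 higher and 1834 lower, with 104 under a term for the flow cell and 5771 with only these tumours in the model. The macrophage list had a median of -0.28 and a mean of 0.58, and the urea cycle and interferon lists had medians of -0.05 and -0.01 with a camera direction of up.

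The 4 Y+mutant and the 4 B+mutant tumours shared a flow cell and were compared directly, a comparison added after the data were seen. Cholangiocyte markers had 11 of 14 higher in Y+mutant, also adjusted over the list alone (median 3.63), a call that held with an estimated correlation (camera adjusted p = 1.98e-09 and 0.017). Wnt target and pericentral genes had 18 of 24 lower and 1 higher, also adjusted over the list alone (median -3.25, also with 1 gene at its bound, camera adjusted p = 2.75e-10, adjusted p = 0.0611 with an estimated correlation), with Tcf7 at 3.25 ± 2.09 against 24.7 ± 5.8 CPM. Without YL the Wnt median was -2.29 (camera adjusted p = 3.06e-06, adjusted p = 0.208 with an estimated correlation). YAP targets had 17 of 22 higher and 2 lower, also adjusted over the list alone (median 1.55, camera adjusted p = 1.4e-08, adjusted p = 0.177 with an estimated correlation). Oxidative phosphorylation genes had 25 of 25 lower, also adjusted over the list alone (median -0.84, camera adjusted p = 8.75e-13, adjusted p = 0.215 with an estimated correlation). NRF2 targets had 15 of 46 lower and 3 higher, also adjusted over the list alone (median -0.50, camera adjusted p = 0.0462, adjusted p = 0.849 with an estimated correlation). Of the 7109 genes called 3831 were higher and 3278 lower, and 4028 were called with only these 8 tumours in the model. The glycolysis and hypoxia lists had medians of 0.17 and 0.14 with a camera direction of down, and the pentose phosphate list a median of -0.28 and a mean of 0.04.

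The 3 comparisons with BY share its 5 libraries, so their calls were compared for overlap. BYL and BYR had 3869 genes called the same way against BY and 0 in opposite ways. BYL and BYW had 1616 the same way and 13 opposite, and BYR and BYW 1471 and 8. Independent lists of these sizes would share 750, 405 and 305. Across genes, which are not independent replicates, Pearson's r between the fold changes was 0.85, 0.53 and 0.59, while simulated groups without any difference that shared their controls gave 0.48, 0.50 and 0.46 and shared 0 called genes at the median. The covariance of the fold changes, which unlike r grows with their size, was 1.08, 0.54 and 0.57. Its simulated means were 0.12, 0.12 and 0.11. Where the BY libraries were split between the comparisons, the median numbers shared were 1909, 613 and 504 and the median r was 0.66, 0.34 and 0.38. In all 3 comparisons 1372 genes were called the same way, of which 198 were called between BY+mutant and BYW. All 3 also set libraries of other flow cells against those of the first. A difference between flow cells could by itself add shared calls, and none of the values above removes it. Of the 3869 genes shared by BYL and BYR, 1627 were called the same way in BY+mutant against BYW, where 20.9% of all genes tested were called in either direction. The same BYL and BYR libraries enter each of these comparisons, so part of this agreement is built in.

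Sex differences were estimated separately in the livers and in the tumours to ask whether tumours keep them. In liver 445 genes differed between 3 females and 2 males, 162 higher in females and 283 in males, and in the tumours 98, with 13 females and 14 males. The BL, BR and YL tumours were all from females, so they add nothing to the estimated sex difference. They do enter the mean CPM of female tumours given below, which thus differ from those of males in plasmids too. The difference between the sex effects was called for 83 genes. Cyp2d9, a male-typical cytochrome P450 gene (gene ID 13105, chromosome 15, 82452377 to 82456827), was at 7.26 ± 5.09 CPM in female and 1660 ± 316 in male liver, and at 125 ± 112 and 411 ± 136 in female and male tumours (log2 female minus male -7.84 ± 0.77 and -1.76 ± 0.35, difference -6.08 ± 0.76, adjusted p = 0.000243). Rcan2, a calcineurin regulator gene, was at 44.4 ± 13.9 and 6.44 ± 2.04 CPM in female and male liver and at 72.9 ± 28.6 and 57.9 ± 15.4 in the tumours. Of 427 autosomal genes called in liver, 32 were called the same way in the tumours and 81 had a called difference. With 2 male livers the count of 83 depends on single animals, at 14 without liver replicate 4, 35 without replicate 5, 51 without replicate 3 and 253 without replicate 2.

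The authors' deposited table holds 15 comparisons of its own, with the 2 mutants of a plasmid set pooled. In the 8 that match those above, calls in both analyses were in opposite directions for 0 genes, and Pearson's r across genes between the fold changes lay between 0.96 and 0.998. The authors' table called fewer genes, for example 1251 between BYW and BY of the 16994 tested here.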

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

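The tests of the wrong label, of mixed RNA, of the transcript level of Nfe2l2, of gene length, of sequencing runs and of neutrophils were chosen only after the results were seen. In each group of 4 or 5 libraries, the mean log2 CPM of every gene list and the levels of single genes, Nfe2l2, Yap1, Ctnnb1, Keap1 and Myc among them, were searched for 1 library far from the others. Of 170 such searches 8 found one, where chance alone marks about 1 in 20, or 8.5.

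BYW replicate 2 had a mean log2 CPM over the NRF2 targets of 8.31, against 5.90 to 6.57 in the 4 other BYW tumours, and over the pentose phosphate genes of 6.09 against 5.07 to 5.31. Nfe2l2 was at 225 CPM, the lowest of the 5 BYW tumours, which argues against more Nfe2l2 transcript in total. The share from the plasmid cannot be told from these counts. A mutant tumour under a wrong label stays open, since it lay nearer the mutant mean at 56.2% of 690 genes called at 4-fold or more, between the mutant tumours (66.3% in BYR replicate 1, at least 83% in the 8 others) and the other BYW tumours (at most 41.9%), each held out of the choice of genes. RNA of a mutant tumour mixed into the sample also stays open, since 34.8% of 46 other genes higher in the mutants lay below the level that its NRF2 targets need (70.6% of mutant RNA), but so did 43.1% in a mutant tumour held out, BYR replicate 1 (0 to 4.2% in the 8 others), which alone keeps this open. Activation of NRF2 by another route, such as a mutation acquired during growth, may explain its targets and was not tested.

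Ribosomal protein genes had a median log2 fold change against BY of -0.44 in BYL, -0.26 in BYR and -0.57 in BYW, all across flow cells. Lists of other genes matched in length had medians as low in 27.5% of 10000 draws for BYL and 65.7% for BYR. A bias with gene length may thus account for the lower medians in both. For BYW the share was 0.1%, but genes were drawn 1 by 1, while ribosomal protein genes may move together. With the length trend removed, genes of at most 600 nt still had a median of -0.23 in BYW, near -0.25 for the ribosomal protein genes. Length as the whole cause is therefore not excluded for BYW. In 4 of 5 comparisons between flow cells the 143 genes of at most 600 nt were lower by more than 0.39, the larger size of their median in the 2 comparisons within a flow cell (-0.93, -0.83 and -0.82 in BYL, BYR and BYW). A difference between sequencing runs and a difference between the tumours cannot be told apart, since each of these groups was on another flow cell than BY.

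Neutrophil markers had a mean log2 CPM of 0.13 in BYR replicate 2, against 2.54 to 2.65 in the 3 other BYR tumours, which were on another flow cell. The flow cells overlapped, at 0.29 (BYW replicate 1) to 3.62 on the second and -0.93 to 1.23 (YR replicate 3) on the third. BYR replicate 2 lay below the 3 other BYR tumours at 9 of 10 neutrophil markers and at 14 of 15 heart muscle markers (Myl2 at 0 CPM against 2.62 to 9.38), but markers of a cell type move together, so each count is 1 observation on 1 library. A term for the flow cell called 0 genes by edgeR, with 303 at an unadjusted p under 0.05 (7 neutrophil and 13 heart muscle markers among them), and 1 gene by DESeq2, with 0 of these markers called lower. Reads or RNA shared among the libraries of the second flow cell may account for part of the neutrophil signal against BY. Neutrophils in those tumours cannot be told apart from it, because the groups differ in flow cell, while Mmp9 at 10.7 CPM and Csf3r at 4.56 in that library were near or within the range of the others (11.3 to 33.0 and 3.17 to 7.02).

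Glycolysis genes had a mean log2 CPM of 6.19 in BYL replicate 1 against 5.67 to 5.75 in the other BYL tumours. Cholesterol synthesis genes were at 7.14 in liver replicate 2 against 7.67 to 7.87. Hypoxia genes were at 3.16 in liver replicate 1 against 3.45 to 3.53. Stellate cell and fibroblast markers were at 4.09 in liver replicate 4 against 4.45 to 4.54, and at 0.51 in BYW replicate 5 against 3.32 to 3.78. The sex difference differed between liver and tumours for 83 genes by edgeR, with 1853 at an unadjusted p under 0.05.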

How the results depend on the processing

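The term for the flow cell, the removal of the gene length trend, the settings without BYW replicate 2 beyond the planned removal of each replicate, and all alternatives of the comparison of Y+mutant with B+mutant were chosen only after the results were seen. Named genes gave 21337 values under the alternatives. Of these 19510 kept their direction and their side of the threshold, 1744 kept the direction but no longer passed, 33 newly passed, 40 changed direction without a call and 10 reversed a call. Most values come from leaving out 1 library, and most genes were named for their calls in the same data. With only the groups compared, 62 of 84 values for BYW against BY no longer passed and 22 stayed the same. With the flow cell term, 79 of 97 for BY+mutant against Y+mutant and 58 of 121 against B+mutant no longer passed, while 15 and 61 stayed the same.

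The NRF2 target list stayed higher in BYL (medians 1.68 to 1.95), BYR (1.51 to 1.73) and BY+mutant against BYW (1.10 to 1.75) wherever its median was computed. It was not computed with DESeq2. Of these comparisons, the flow cell term was fitted only for BY+mutant against BYW. With the estimated correlation, camera called the list in none of them. In BYW against BY its median was 0.20 (adjusted p = 0.186) to 0.57 when single replicates were left out, the lowest without BYW replicate 2, and 0.19 with only the BYW and BY libraries and without that tumour (adjusted p = 0.0772).

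DESeq2 called 4 genes between BYL and BYR in place of 0, and 291 for the sex difference between liver and tumours in place of 83. With only the groups compared, each with its own mean, 238 genes were called between BYW and BY in place of 2360 (92 also without BYW replicate 2), 3 between BYL and BYR, 5771 between BY+mutant and Y+mutant in place of 3414 and 4028 between Y+mutant and B+mutant in place of 7109. The cause was not tested. With fewer samples, females alone gave 3369 genes for BYL and 2318 for BYR against BY (5813 and 4388 with all samples), 680 for BYW against BY (with 1 BYW female, replicate 4, assumed to vary like the other groups), 2 for BYL against BYR, 618 for BY+mutant against BYW and 2179 for BY+mutant against Y+mutant. Males alone gave 5583 for BY against liver, 3220, 1740 and 779 for BYL, BYR and BYW against BY, 1334 for BY+mutant against BYW and 1298 for BY+mutant against Y+mutant. The flow cell term left 1828 of 7660 genes for BY+mutant against B+mutant and 104 of 3414 for BY+mutant against Y+mutant, and its only bridge within a group is BYR replicate 2.

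Leaving out single replicates gave 2343 (without BL replicate 2) to 4827 genes for B+mutant against liver, 2850 (without BYR replicate 4) to 4307 for BYR against BY, 0 to 1 (without BYL replicate 5) for BYL against BYR and 14 (without liver replicate 4) to 253 (without liver replicate 2) for the sex difference. That count was 51 without liver replicate 3 and 35 without replicate 5. The other counts stayed within 1.5 times when any 1 replicate was left out.

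With the correlation between genes estimated, camera called 0 lists where the preset called 19 for BY against liver, 13, 15 and 10 for BYL, BYR and BYW against BY, 10 for BYL against BYR, 15 for BY+mutant against BYW, 11 for B+mutant and 20 for Y+mutant against liver and 19 for BY+mutant against B+mutant. It called 2 of 11 for BY+mutant against Y+mutant and 1 of 17 for Y+mutant against B+mutant. With the BY libraries split between comparisons, the shared calls fell from 3869 to 1909 for BYL and BYR, from 1616 to 613 for BYL and BYW and from 1471 to 504 for BYR and BYW, where fewer controls enter each fit.

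These named genes reversed, and except for Afp the cause was not tested. Among females the log2 fold change of Thrsp in BYL against BY was 0.38 in place of -1.99, and in BYW against BY those of Afp and Clec4g were -1.18 and 0.29 in place of 4.93 and -2.17. The only BYW female is replicate 4, so those 2 values rest on 1 library, and the high Afp of the male BYW replicate 2 is left out. Afp was at -1.06 without BYW replicate 2 (range without single replicates to 5.42) and at -0.88 with only the groups compared and without it. Among males Ms4a1 in BY against liver was at 4.92 in place of -2.25. With the flow cell term S100a8 and S100a9 in BY+mutant against B+mutant were at -0.04 and -0.06 in place of 3.48 and 3.93, and Psmc2 and S100a8 in BY+mutant against Y+mutant at -0.03 and -0.72 in place of 0.25 and 2.87. RLE factors moved the median of all genes between BY and liver from 0.12 to 0.07.

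Depth limits genes near the floor, where 3 counts over an arm bound the fold.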

Other observations

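The splits of the libraries for Y+mutant against B+mutant were chosen only after that result was seen, and those for the 10 other comparisons before. The counts here come from models of the libraries compared with 1 mean per arm, while those given above with only the groups compared keep a mean per group, so the 2 differ where an arm pools groups. Other splits of the same libraries gave as many genes as the real grouping in 1 of 40 cases, the real one itself, for BY against liver (8213 genes, highest other split 1), BYL against BY (5454 and 0), BYR against BY (3871 and 575), BY+mutant against BYW (3197 and 0), B+mutant against liver (3592 and 8), Y+mutant against liver (8112 and 3203), BY+mutant against B+mutant (7219 and 0) and BY+mutant against Y+mutant (4050 and 0). The same held in 1 of 35 splits for Y+mutant against B+mutant (3763 and 0). No other split drawn thus reached the real count in these 9 comparisons, and 1 in 40 or 1 in 35 is the smallest share such draws can give. Splits that mix the arms also carry any difference between them as spread, which lowers their counts. For BYL and BYR against BY, and for B+mutant and Y+mutant against liver, the real split is also one between flow cells. For BYW against BY (238 genes) 2 of 40 splits were as large, the highest other with 407, and for BYL against BYR (3 genes by edgeR, with 529 at an unadjusted p under 0.05 in the model of all samples) also 2 of 40, the highest other with 43, so chance cannot be excluded for either. The split of 407 genes set BYW replicates 1 and 3 with BY replicates 1, 2 and 3 and points to a structure of the samples that the groups do not describe. Those libraries lay at 37.7 to 58.4 on the first principal component, the other BYW and BY libraries at 2.9 to 21.6. Their mean log2 CPM over the hepatocyte identity genes was 9.16 to 10.02, against 10.1 to 10.61 in the others. The split of 3203 genes differs from the real one by liver replicate 3 alone, which it set with the Y+mutant tumours.

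Igf2, the fetal growth factor gene (gene ID 16002, chromosome 7, 142650768 to 142666816), and Afp, chosen here after their values were seen, varied between tumours. The YL tumour, the only one of its plasmids, had 13200 CPM of Igf2 and 17100 of Afp, against 3.71 to 166 and 249 to 387 in the 3 YR tumours. Within the BYW group replicate 2 had 813 and 2680 CPM, and BYW replicate 4 had 100 CPM of Igf2 with 8.26 of Afp.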
